A study of Homo sapiens with 2 samples.

How the data were processed

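Small RNA was sequenced from MCF7-TAMR cells, a tamoxifen-resistant derivative of the MCF-7 human breast cancer line, in 1 control library and 1 CUL4B knockdown library. Per the labels' protocols, total RNA was extracted with Trizol, adapters were ligated to the ends of small RNAs, cDNA was amplified by PCR, and fragments of small RNA size were recovered from a gel. Per the submitters' processing notes, Bowtie and the human build hg38 are named; the version, the miRNA annotation release, the counting tool and the filters are not given in the sources used here. The table deposited by the authors lists 1535 entries, of which 1458 are mature human miRNAs and 77 are unannotated entries.

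Per the file headers, each library has a read count column and a TPM column. The deposited read counts are whole numbers, and no molecular identifiers are mentioned in the labels. The deposited TPM of an entry equalled its read count scaled to a column total of 1000000, to within 4.6e-05 TPM, so the values carry no length term and depend on the most abundant miRNAs through the total. Every row named a miRNA or an unannotated entry. The total was 5446599 reads in the control library and 4992866 in the knockdown library, so that 1 read was worth 0.184 TPM in the control and 0.200 TPM in the knockdown library. A count of 0 allows up to 3 reads, which is 0.551 TPM in the control and 0.601 TPM in the knockdown library. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

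The comparison was the knockdown library against the control library. Before the data were examined, the pseudocount, the expression minimum, the fold threshold, the miRNA lists, the markers of other cell types, the rule for named miRNAs and the alternatives were fixed. Fold changes were computed as log2 of (TPM + 1) in the knockdown over (TPM + 1) in the control, which understates the change of miRNAs of low abundance. Entries with a mean TPM of at least 10 over the libraries were compared, and a difference of at least 2-fold was counted. Ratios of TPM without a pseudocount are given with exact conditional binomial (Clopper-Pearson) 95% intervals, and shares of reads with Wilson 95% intervals. With 1 library per group there is no replicate check, no dispersion can be estimated and no test of the knockdown against the control was made; every difference describes these libraries. The design had been fixed for TPM values; the table also held read counts, which were used for intervals and for the Fisher test. The planned Fisher's exact test on read counts with Benjamini-Hochberg adjustment compares the libraries, not the conditions, and only its counts of entries are given.

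For each list with at least 3 members at a mean TPM of at least 10, the median log2 fold is given with its distribution-free interval over members (the range where members are fewer than 6) and with its percentile among 10000 random lists of the same size drawn from the same 5 expression bins. Lists of stems took both arms of a miRNA, and lists of arms took the named arm. A mature miRNA made from several loci was counted once. Named miRNAs were the 12 with the largest positive and the 12 with the largest negative log2 fold, the 6 most abundant, the members of the CUL4B-linked list, and up to 4 members per list with the largest absolute log2 fold. Markers of other cell types are given by name, and other miRNAs named in the account of hairpin arms were chosen after their values were seen.

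Hairpin genes were taken by name from GENCODE release 29 on GRCh38, the assembly that hg38 names; 1428 of the 1458 mature human entries matched a hairpin gene. Coordinates are 1-based positions of hairpin genes on this build, and exon or intron refers to a GENCODE gene on the same strand that spans the hairpin. Hairpins overlapping on opposite strands were paired, 5p arm with 3p arm, where each library had at least 100 reads for the pair. An entry without an arm in its name was paired with the most abundant entry of each opposite hairpin name. Counts were called near-equal when they agreed within 2% in both libraries.

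The code was tested on simulated data drawn from the mean expression of the libraries, with 293 entries past the expression minimum. The 95% intervals held the true ratio for 95.9% of these entries. All 9 entries simulated at 4-fold higher and all 11 at 2-fold higher passed the adjusted Fisher threshold of 0.05 in the right direction, as did all 8 at 0.5-fold and all 5 at 0.25-fold. Of 260 unchanged simulated entries, 0 were at least 2-fold apart from counting error.

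Alternatives were other pseudocounts (0.1 and 10), no expression minimum or one of 100 TPM, centring on the median log2 fold, rescaling without the 10 most abundant miRNAs, leaving out the unannotated entries, and thresholds of 1.5-fold and 4-fold. One alternative, leaving out the less abundant entry of each near-equal opposite-strand pair, was added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.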

Results

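Mature miRNAs were profiled by small RNA sequencing in MCF7-TAMR cells carrying a CUL4B knockdown and in control cells. CUL4B is a scaffold of cullin-RING E3 ubiquitin ligases. Each group had 1 library, so the intervals cover counting error only. Variation between cultures and library preparations is part of the values but could not be estimated. The read counts summed to 5446599 over 1043 entries with at least 1 read in the control library. In the knockdown library they summed to 4992866 over 1059 entries. Both libraries had reads for 871 entries, and 304 entries were at 0 in both. The table contained 0 entries for CUL4B itself, so the extent of the knockdown was not analysed here.

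miR-21-5p, an oncogenic miRNA abundant in breast cancer cells, was the most abundant miRNA in both libraries. It accounted for 36.9% of control reads (Wilson 95% interval 36.8 to 36.9%) and 44.5% of knockdown reads (44.5 to 44.5%). miR-148a-3p, which targets DNMT1, accounted for 21.0% of control reads (21.0 to 21.0%) and 15.1% of knockdown reads (15.1 to 15.1%). let-7f-5p made up 5.75% of control (5.73 to 5.77%) and 5.23% of knockdown reads (5.21 to 5.25%). let-7i-5p made up 3.11% of control (3.10 to 3.13%) and 4.06% of knockdown reads (4.04 to 4.08%). miR-7-5p made up 4.76% of control reads (4.74 to 4.78%) and 2.30% of knockdown reads (2.29 to 2.31%). miR-3529-3p was listed at nearly the same level as miR-7-5p, at 4.75% of control (4.73 to 4.77%) and 2.29% of knockdown reads (2.28 to 2.31%); its hairpin lies opposite MIR7-2 on chromosome 15, and whether these entries are separate measurements is uncertain. The 10 most abundant entries took 83.2% of control reads (83.2 to 83.2%) and 80.0% of knockdown reads (79.9 to 80.0%). All these shares are of column totals. In these totals the second entries of near-equal opposite-strand pairs held 5.65% of control and 3.47% of knockdown reads. Reads counted for both strands would make these totals too large, which the Wilson intervals do not cover. The 77 unannotated entries together held 269 reads in the control and 241 reads in the knockdown library.

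The knockdown library had 111 times as much miR-34c-5p and 22.6 times as much miR-143-3p as the control library, and also more miR-210-3p, miR-451a, miR-21-3p and miR-652-5p. It had less of several miR-548 family members, miR-7706, miR-7974, miR-3158, miR-582-3p, miR-151a-3p and miR-7-5p. Among 298 entries with a mean TPM of at least 10, 26 were at least 2-fold higher and 14 at least 2-fold lower in the knockdown library, and 258 (86.6%) were less than 2-fold apart. The log2 abundances of the libraries correlated with a Pearson r of 0.968 across these entries, which are not independent replicates. The median log2 fold was 0.19 (95% interval over entries 0.10 to 0.25), so that most entries, 192 of 298, were higher in the knockdown library by some amount. Centring on this median gave 17 higher and 19 lower entries, and the share of higher entries among those at least 2-fold apart moved from 65.0% to 47.2%. Rescaling without the 10 most abundant miRNAs shifted the median by -0.27, to -0.08, and gave 16 higher and 22 lower entries (42.1% higher). That run covers the 288 entries left, and the 10 left out include the lower entries miR-7-5p, miR-3529-3p and miR-151a-3p. Ratios are on the deposited scale, and a ratio near 1 gives no direction across these scalings. By Fisher's exact test on reads with Benjamini-Hochberg adjustment at 0.05, 213 entries differed between these libraries, 141 higher and 72 lower, and all 40 entries at least 2-fold apart were among them. That test compares the libraries and says nothing about the spread between cultures. The interval of the ratio lay wholly above 2 for 21 of the 26 higher entries and wholly below 0.5 for 12 of the 14 lower entries.

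**Figure D1:**
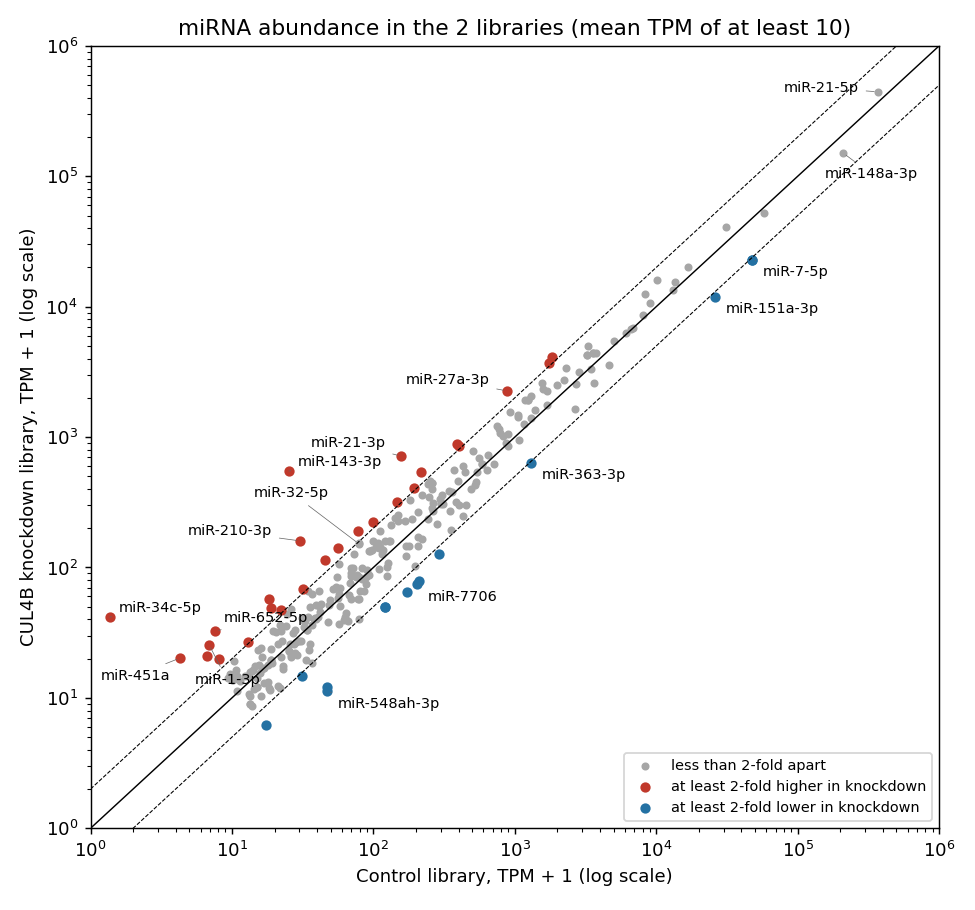
Abundance of the 298 entries with a mean TPM of at least 10 in the control library (x axis, TPM + 1, log scale) and in the CUL4B knockdown library (y axis, TPM + 1, log scale), 1 point per entry; the solid line marks equal values and the dashed lines a 2-fold difference. Red points (26) are at least 2-fold higher and blue points (14) at least 2-fold lower in the knockdown library, with miR-34c-5p and miR-143-3p farthest above the line.

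The largest ratio belonged to miR-34c-5p, a p53-induced miRNA that represses cell cycle genes. It had 203 reads (40.7 TPM) in the knockdown and 2 reads (0.367 TPM) in the control library, a ratio of 111 with a counting interval of 30.3 to 920.5. Its hairpin gene MIR34C spans chromosome 11, 111513439 to 111513515, on the plus strand. By contrast miR-34b-3p, also on the p53-responsive list and named after its value was seen, had 3 reads against 1. Its ratio of 3.27 (0.263 to 172) has an interval that includes equality. miR-143-3p, abundant in smooth muscle and fibroblasts, was at 548 TPM (2734 reads) against 24.2 TPM (132 reads), a ratio of 22.6 (18.97 to 27.1). MIR143 lies at chromosome 5, 149428918 to 149429023, in an exon of the long non-coding RNA CARMN. miR-210-3p, the main hypoxia-induced miRNA and the member of the hypoxia list past the expression minimum, was at 159 TPM against 29.2 TPM, a ratio of 5.45 (4.59 to 6.50). MIR210 lies at chromosome 11, 568089 to 568198, in an intron of MIR210HG.

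Further down the list of higher miRNAs, miR-451a, an erythroid miRNA, was at 19.2 TPM against 3.30 TPM (ratio 5.82, 3.49 to 10.2), on 96 and 18 reads. miR-652-5p, from an intron of TMEM164 on chromosome X (110055329 to 110055426), was at 31.4 TPM against 6.61 TPM (4.76, 3.29 to 7.04). miR-21-3p, the minor arm of the MIR21 hairpin in an exon of VMP1 (chromosome 17, 59841266 to 59841337), was at 715 TPM against 156 TPM, a ratio of 4.60 (4.26 to 4.96). The major arm miR-21-5p differed by only 1.21 (1.20 to 1.21). miR-1-3p, a striated muscle miRNA, was at 24.6 TPM against 5.88 TPM (4.19, 2.82 to 6.40). miR-181c-3p had a ratio of 3.52 (2.33 to 5.45), and miR-424-5p, an X-linked member of the cell-cycle repressing miR-15/16 family, a ratio of 3.28 (2.59 to 4.19). miR-4454 (2.70, 2.12 to 3.45), miR-27a-3p (2.58, 2.49 to 2.67) and miR-205-5p, typical of basal epithelium (2.54, 2.18 to 2.97), completed the 12 highest.

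Among the lower miRNAs, miR-548ah-3p was at 10.2 TPM against 45.9 TPM (0.223 times the control level, 0.161 to 0.302) and miR-548p at 11.0 TPM against 46.3 TPM (0.238, 0.175 to 0.320). miR-548o-3p was at 77.1 TPM against 209 TPM (0.368, 0.327 to 0.414) and miR-548f-3p at 13.6 TPM against 30.1 TPM (0.452, 0.336 to 0.604; log2 fold -0.76 at a pseudocount of 10, under 2-fold). The miR-548 family comes from many near-identical hairpins, so reads may be shared among these entries and their separate levels are uncertain. miR-1306-3p, whose hairpin lies in an exon of DGCR8 (chromosome 22, 20086058 to 20086142), was at 5.21 TPM against 16.3 TPM (0.319, 0.198 to 0.498; log2 fold -0.79 at a pseudocount of 10, under 2-fold). miR-7706, from an exon of AKAP13, was at 73.3 TPM against 203 TPM (0.361, 0.320 to 0.406), and miR-7974 at 63.9 TPM against 172 TPM (0.371, 0.326 to 0.422). miR-3158-3p and miR-3158-5p had ratios of 0.407 (0.350 to 0.472) and 0.409 (0.352 to 0.475); their hairpins overlap each other on opposite strands of chromosome 10 (101601417 to 101601497), and their counts were near-equal. miR-582-3p, from an intron of PDE4D, had a ratio of 0.432 (0.394 to 0.474).

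Abundant miRNAs were also among the lower ones. miR-151a-3p, from an intron of PTK2 (chromosome 8, 140732564 to 140732653), was at 11886 TPM against 26094 TPM, a ratio of 0.455 (0.451 to 0.460). miR-7-5p, which targets EGFR, was at 23002 TPM against 47595 TPM, a ratio of 0.483 (0.480 to 0.487), and miR-3529-3p gave 0.483 (0.480 to 0.487). miR-7-5p is made from hairpins on chromosomes 9, 15 and 19, which the mature sequence does not separate.

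miR-32-5p was put on the CUL4B-linked list from recall of this study's own paper, which was not consulted here. In the knockdown library miR-32-5p was 1.94-fold higher (1.72 to 2.19), at 151 TPM against 77.8 TPM on 754 and 424 reads. Its log2 fold of 0.95 was below the 2-fold threshold and 0.76 above the median of all entries. The other arm of the hairpin, miR-32-3p, named after its value was seen, was lower, at 20.4 TPM against 27.7 TPM (log2 fold -0.42). MIR32 lies in an intron of TMEM245 (chromosome 9, 109046229 to 109046298). Of the other members of the CUL4B-linked list, miR-194-5p was at 51.9 TPM against 41.9 TPM (1.24, 1.03 to 1.49). miR-33b-5p had 0 reads in the knockdown and 1 read in the control library. miR-372-3p and miR-373-3p had 0 reads in both libraries, which allows up to 0.601 TPM in the knockdown and 0.551 TPM in the control library, and miR-300 was not analysed here. The list included miR-32-5p because of the study itself, so its direction there is not independent evidence. In the seed family that miR-32-5p belongs to, miR-92a-3p was 1.46-fold higher (1.42 to 1.49) and miR-363-3p was at 0.484 times the control level (0.464 to 0.505). miR-92b-3p differed by 1.05 (0.989 to 1.12), an interval that includes equality, and its log2 fold was -0.11 after centring and -0.21 after rescaling. The median of the 5 members was 0.08, at the 23.0th percentile of random lists, and was -0.11 after centring and -0.21 after rescaling.

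The p53-responsive list had the highest median among the lists with at least 3 members, a rank that rested on miR-143-3p. Of its 6 members past the expression minimum, 3 were at least 2-fold higher, 0 were at least 2-fold lower and 3 were less than 2-fold apart. miR-34a-5p, the best known p53 target among miRNAs, was at 221 TPM against 98.4 TPM (2.24, 2.02 to 2.49), beside miR-34c-5p and miR-143-3p. The log2 fold of miR-34a-5p was 0.97 after centring and 0.88 after rescaling, under 2-fold, which leaves 2 of the 6. miR-107 was 1.82-fold higher (1.68 to 1.98), while miR-192-5p, named after its value was seen because it was lower, was at 0.718 times the control level (0.646 to 0.796). The median log2 fold was 1.01 (range -0.48 to 4.93), at the 99.7th percentile of random lists, and 0.82 after centring. miR-143-3p is also a marker of fibroblasts and smooth muscle. Without it the median of the 5 other members was 0.86, at the 98.3rd percentile and below the 0.92 of the miR-29 family. These 5 still include miR-34c-5p, which passed the expression minimum only through the knockdown library (40.7 against 0.367 TPM). The list was singled out as the highest of 17 medians, with no allowance for that choice. Neither percentile is therefore a test of p53-responsive miRNAs as a group.

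**Figure D2:**
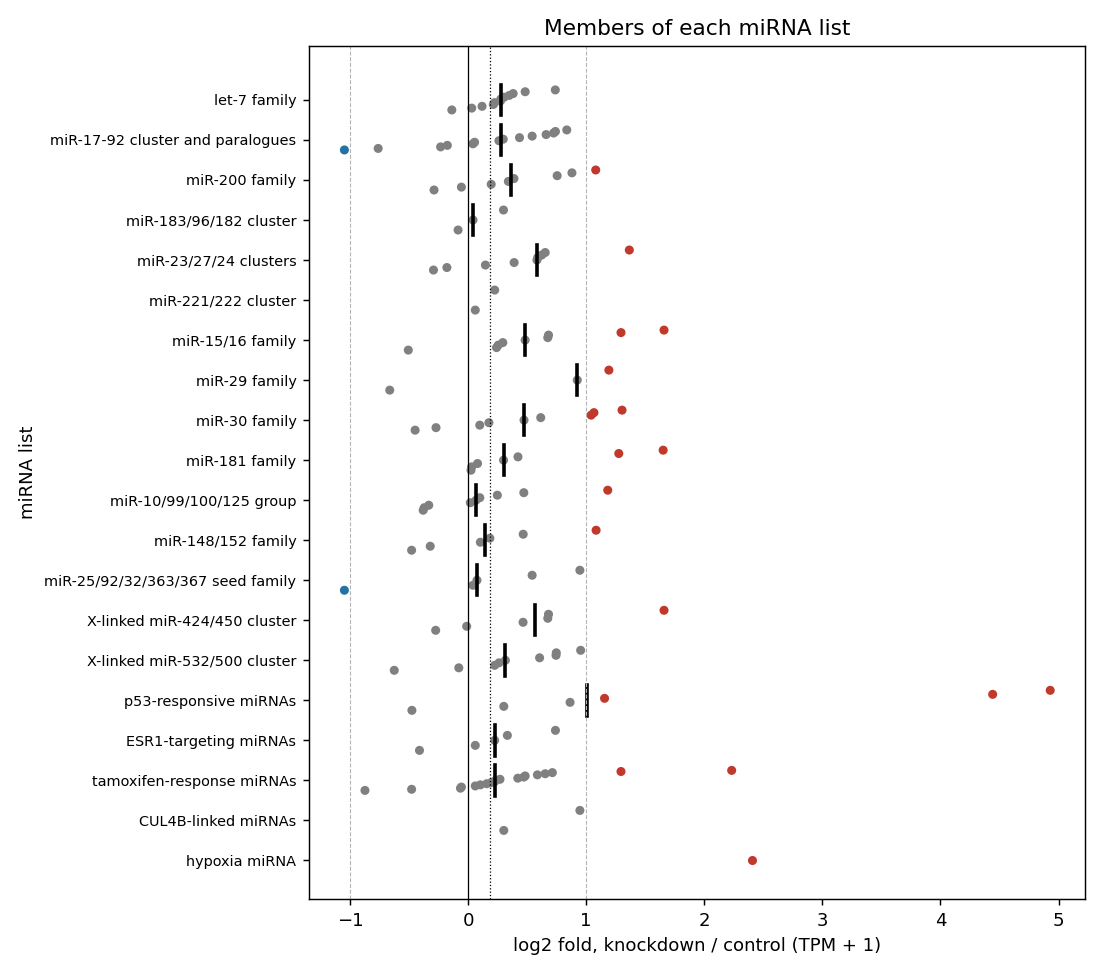
The log2 fold (knockdown over control, TPM + 1) of each member with a mean TPM of at least 10, by list; 1 point per miRNA, red at least 2-fold higher, blue at least 2-fold lower, grey less than 2-fold apart. Thick bars mark the median of lists with at least 3 members, the dotted line marks the median of all 298 entries (0.19) and dashed lines a 2-fold difference; the p53-responsive list, which holds miR-143-3p, has the highest median, 1.01.

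In the miR-29 family, which targets DNA methyltransferases and matrix genes, miR-29a-3p was 2.29-fold higher (2.17 to 2.41) and miR-29b-3p 1.93-fold higher (1.60 to 2.32), while miR-29c-5p, an arm without the family seed, was at 0.626 times the control level (0.521 to 0.750). The median of its 3 members was 0.92, at the 97.8th percentile, with a range of -0.66 to 1.19; the log2 fold of miR-29a-3p was 0.91 after rescaling, under 2-fold. In the miR-30 family, 3 of 9 members were at least 2-fold higher and 0 at least 2-fold lower. These were miR-30e-5p (2.48, 2.31 to 2.65), miR-30a-5p (2.10, 1.95 to 2.26) and miR-30d-3p (2.15, 1.58 to 2.94); the median was 0.47, at the 90.6th percentile. Only miR-30e-5p of these 3 stayed past 2-fold after centring or rescaling, since miR-30a-5p was at a log2 fold of 0.88 and 0.79 and miR-30d-3p at 0.85 and 0.81. In the miR-15/16 family 2 of 9 members were at least 2-fold higher and 0 at least 2-fold lower, namely miR-424-5p and miR-15a-5p (2.66, 1.81 to 3.96). miR-15a-5p had 7.16 TPM in the control library and was under 2-fold at a pseudocount of 10 (log2 fold 0.76). Under the expression minimum, miR-195-3p, named after its value was seen, had 23 against 63 reads (0.398, 0.236 to 0.651). There miR-15a-3p, miR-16-1-3p, miR-497-5p and miR-503-3p were higher by a log2 fold under 1. The median of that family was 0.48 (0.24 to 1.30), at the 90.2nd percentile. In the miR-181 family 2 of 7 members were at least 2-fold higher, miR-181c-3p and miR-181d-5p (2.44, 2.17 to 2.74), with a median of 0.30 at the 72.2nd percentile. The log2 fold of miR-181c-3p was 0.94 at a pseudocount of 10, under 2-fold.

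The let-7 family holds tumour suppressors restrained by LIN28. All 12 members were less than 2-fold apart, the largest difference being let-7b-5p at 1.67 (1.61 to 1.73), and the median of 0.28 (0.12 to 0.38) lay at the 63.4th percentile. Among the proliferation-linked miR-17-92 cluster and its paralogues, 0 of 14 members were at least 2-fold higher and 1 was at least 2-fold lower, with a median of 0.28 at the 71.8th percentile. There miR-106b-5p (1.79, 1.67 to 1.92) stood opposite the X-linked members miR-363-3p and miR-106a-5p (0.584, 0.487 to 0.698), which passed 2-fold lower after rescaling (log2 fold -1.06). Of the miR-23/27/24 clusters, 1 of 9 members was at least 2-fold higher, miR-27a-3p, and miR-27b-3p was 1.57-fold higher (1.56 to 1.59); the median was 0.58 at the 96.2nd percentile. In the DNMT1-targeting family of miR-148 and miR-152 the 3p arms of miR-148b and miR-148a differed in direction. Here miR-148b-3p was 2.12-fold higher (2.07 to 2.17) and miR-148a-3p was at 0.718 times the control level (0.716 to 0.720). The third 3p arm, miR-152-3p, named after its value was seen, was at 1.08 times the control level (1.04 to 1.11), a log2 fold of -0.08 after centring. The log2 fold of miR-148b-3p was 0.90 after centring and 0.80 after rescaling, under 2-fold. The family median of 0.14, at the 37.9th percentile, was -0.04 after centring and -0.10 after rescaling.

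Of the 8 members of the epithelial miR-200 family, 1 was at least 2-fold higher, miR-200a-3p (2.12, 2.01 to 2.23), and 0 were at least 2-fold lower. The log2 fold of miR-200a-3p was 0.89 after centring and 0.80 after rescaling, under 2-fold, and the other arm of its hairpin, miR-200a-5p, named after its value was seen, was at 0.819 times the control level (0.774 to 0.866). miR-429 was 1.84-fold higher (1.72 to 1.97) and miR-141-3p 1.69-fold higher (1.55 to 1.85), and the most abundant member, miR-200c-3p, was 1.15-fold higher (1.13 to 1.16) and has no value after rescaling, being among the 10 entries left out. miR-200b-3p was at 0.962 times the control level (0.942 to 0.982). The family median was 0.37, at the 77.1st percentile. The cluster of miR-183, miR-96 and miR-182 had 0 of 3 members at least 2-fold apart, and its median of 0.04, at the 23.4th percentile, was -0.14 after centring and -0.24 after rescaling. In the group of miR-10, miR-99, miR-100 and miR-125 1 of 9 members was at least 2-fold higher, miR-125a-5p (2.27, 2.22 to 2.33), whose log2 fold was just under 1 after centring and 0.90 after rescaling, while miR-99a-5p (0.773, 0.759 to 0.788) and miR-10a-5p (0.768, 0.709 to 0.831) were lower; the median of 0.07, at the 22.4th percentile, was -0.12 after centring and -0.20 after rescaling.

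Of the X-linked clusters, that of miR-424 and miR-450 had 1 of 6 members at least 2-fold higher and a median of 0.57, at the 91.9th percentile, with miR-503-5p at 1.61 (1.44 to 1.80). The cluster of miR-532 and miR-500 had 0 of 9 members at least 2-fold apart and a median of 0.32, at the 81.9th percentile, with miR-660-5p at 1.95 (1.73 to 2.20) and miR-500a-5p at 0.642 (0.531 to 0.775). The imprinted chromosome 14 cluster (28 entries) and the chromosome 19 primate cluster with miR-371 to miR-373 (17 entries) had 0 entries past the expression minimum.

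Of the miRNAs chosen for the hormone response, miR-221-3p (1.18, 0.929 to 1.49) and miR-222-3p (1.05, 0.778 to 1.40), which target ESR1 and CDKN1B, had intervals that include equality, and after rescaling their log2 folds were -0.05 and -0.22. Of 5 ESR1-targeting miRNAs, 0 were at least 2-fold apart; miR-18a-5p was 1.71-fold higher (1.32 to 2.21) and miR-193b-3p at 0.751 times the control level (0.686 to 0.821). The median of 0.23, at the 59.5th percentile, was -0.05 after rescaling and -0.04 at a minimum of 100 TPM. Of 19 tamoxifen-response miRNAs, 2 were at least 2-fold higher, miR-451a, which is also a blood cell marker, and miR-15a-5p, and 0 were at least 2-fold lower. Both passed the expression minimum only through the knockdown library, being at 3.30 and 7.16 TPM in the control. In that list miR-375-3p was 1.64-fold higher (1.59 to 1.69) and miR-342-3p at 0.545 times the control level (0.504 to 0.589), with a log2 fold of -1.06 after centring and -1.16 after rescaling, past 2-fold lower; miR-15a-5p was under 2-fold at a pseudocount of 10 (log2 fold 0.76). The median was 0.23, at the 56.4th percentile. The list was drawn up from miRNAs linked to tamoxifen response in either direction, so its median cannot show whether the response shifted.

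Markers of cell types other than luminal epithelium were measured in both libraries. The luminal markers were abundant in both, summing to 22954 TPM in the control and 26999.5 TPM in the knockdown library, and 1 of 8, miR-200a-3p, was at least 2-fold higher on the deposited scale, with miR-203a-3p at 1.24 (1.21 to 1.26) and miR-342-3p at 0.545 (0.504 to 0.589). After centring, 0 of the 8 were at least 2-fold higher and 1, miR-342-3p, was at least 2-fold lower (log2 fold -1.06). Among fibroblast and smooth muscle markers, miR-143-3p stood beside miR-145-5p from the same locus, with 31 reads against 1 read (ratio 33.8, 5.64 to 1378), and miR-199a-5p with 49 against 13 reads (4.11, 2.20 to 8.26). miR-199a-3p (1.27, 0.941 to 1.72), miR-199b-5p (1.16, 0.694 to 1.94) and miR-214-3p, with 3 against 1 reads, had intervals that include equality, as did miR-145-3p with 1 against 2 reads. Among blood cell markers beside miR-451a, miR-150-5p had 10 reads against 0, miR-223-3p 5 against 0, and miR-486-5p 38 against 40 (1.04, 0.647 to 1.66; log2 fold -0.14 after centring). miR-142-3p had 6 against 5 reads, miR-142-5p 6 against 4, miR-144-3p 1 against 0 and miR-144-5p 0 against 1. The endothelial marker miR-126-3p was at 543 TPM against 542 TPM (1.00, 0.952 to 1.06; log2 fold -0.18 after centring), while its minor arm miR-126-5p had 48 reads against 10 (5.24, 2.62 to 11.6). Beside miR-1-3p, the muscle markers miR-133a-3p had 5 reads against 0 and miR-206 had 4 against 2, and miR-133b had 0 in both. The liver and serum marker miR-122-5p was level (0.975, 0.783 to 1.21). Of the neural markers, miR-9-5p was 1.51-fold (1.42 to 1.60), miR-9-3p 1.95-fold (1.37 to 2.80) and miR-128-3p 1.48-fold (1.44 to 1.52) higher, and miR-124-3p had 0 reads in both libraries.

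Both arms of 68 hairpins passed the expression minimum, leaving out near-equal opposite-strand entries. Hairpins named here were chosen after their values were seen. The arms differed by at least 2-fold in their knockdown to control fold in 13 of them. miR-21 had the widest gap, with a log2 fold of 0.27 for the 5p and 2.19 for the 3p arm, and miR-652 the widest in the other direction, with 2.09 for the 5p and 0.31 for the 3p arm. Fisher's exact test of arm by library, with Benjamini-Hochberg adjustment at 0.05 over the 68 hairpins, called 37, which again compares these libraries and not the conditions.

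**Figure D3:**
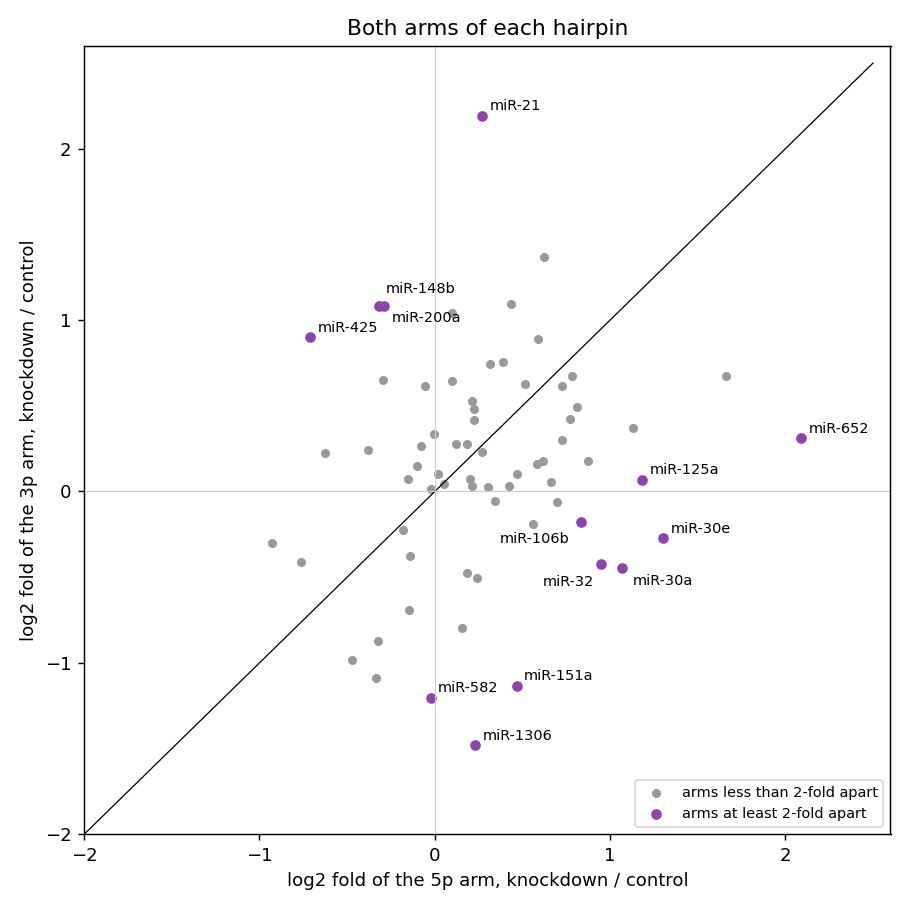
The log2 fold (knockdown over control, TPM + 1) of the 5p arm (x axis) against that of the 3p arm (y axis) for 68 hairpins with both arms at a mean TPM of at least 10; the diagonal marks equal folds. Purple points are the 13 hairpins whose arms differ by at least 2-fold, among them miR-21 above and miR-652 below the diagonal.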

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

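No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out and no other split of the libraries could be made. The number of entries at least 2-fold higher (26) became 62 with no expression minimum, 12 with a minimum of 100 TPM, 17 after centring, 16 after rescaling without the 10 most abundant miRNAs, 69 at a threshold of 1.5-fold and 6 at 4-fold. The number at least 2-fold lower (14) became 33 with no minimum, 8 at 100 TPM, 22 after rescaling, 33 at 1.5-fold and 1 at 4-fold. The median log2 fold (0.19) became 0.056 with no minimum, 0 by construction when centred and -0.081 after rescaling, where 42.1% of the entries at least 2-fold apart were higher. Stricter or looser minima and thresholds admit fewer or more entries by construction, and centring shifts every log2 fold by the same amount. Rescaling shifts each log2 fold by an amount that depends on abundance through the pseudocount, and its counts and medians cover only the 288 entries left. Rescaled list medians thus lack the members among the 10 left out, such as let-7f-5p, let-7i-5p and miR-148a-3p. The cause was not tested further. List medians that left the interval over their members were those of the let-7 family (0.089 centred, 0.0017 rescaled), the cluster of miR-183, miR-96 and miR-182 (-0.14 centred, -0.24 rescaled) and the tamoxifen-response list (0.045 centred, 0.061 rescaled). After rescaling the same held for the miR-15/16 family (0.20) and the miR-181 family (0.017). Of 17 list medians, 5 changed sign in at least 1 alternative, all of them below 0.25 in the main comparison. Of 92 named miRNAs, of which 84 had a value after rescaling, 58 at a minimum of 100 TPM and 90 without the opposite-strand entries, 5 changed sign where a value was given, namely miR-126-3p, miR-183-5p, miR-221-3p, miR-222-3p and miR-92b-3p; of the 36 at least 2-fold apart, 0 changed sign where a value was given, 6 were less than 2-fold apart after centring, 7 after rescaling and 5 at a pseudocount of 10 (miR-1306-3p, miR-15a-5p, miR-181c-3p, miR-30d-3p and miR-548f-3p). In turn miR-342-3p passed 2-fold lower after centring and rescaling, and miR-106a-5p after rescaling. miR-21-5p and miR-200c-3p, whose log2 folds of 0.27 and 0.20 are small, had no value after rescaling. Leaving out the near-equal opposite-strand entries, chosen after seeing the data, left the same 26 higher entries and 12 of the 14 lower ones; it removed miR-3529-3p and miR-3158-5p, and miR-4473 and miR-576-3p, named after their values were seen, passed 2-fold instead. Pseudocounts of 0.1 and 10 and annotated miRNAs alone moved no count by over 1.5 times. At a pseudocount of 10, however, 13 of the 92 named log2 folds left their counting interval, while at 0.1 all 92 stayed within it. Depth limits the low entries: 10 TPM is 54.5 reads in the control and 49.9 in the knockdown library, while the absence of replicates limits all of them.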

Other observations

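The tests of blood cell markers, of pooled markers of other tissues and of opposite-strand pairs were chosen after their values or similar values had been seen; the other tests were written before.

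The hairpins named here were chosen after their values were seen. In 13 of 68 hairpins with both arms at a mean TPM of at least 10, the folds of the 5p and 3p arm differed by at least 2-fold, and in 24 of 68 they had opposite signs on the deposited scale. For miR-32, the log2 fold was 0.95 for the 5p arm and -0.42 for the 3p arm (miR-32-3p, 20.4 TPM in the knockdown against 27.7 TPM in the control library). miR-30e and miR-30a behaved alike, with log2 folds of 1.30 and 1.07 for the 5p arms and -0.27 and -0.45 for the 3p arms. miR-151a-5p had a log2 fold of 0.47 against -1.13 for miR-151a-3p, and miR-425-3p 0.90 against -0.71 for miR-425-5p. Across hairpins, which are not independent replicates, the folds of the arms correlated with a Pearson r of 0.13 and a Spearman rho of 0.14; this r lay at the 86.0th percentile of random pairings, whose central 95% reached 0.24. Entries from different hairpins within 10000 bp on the same strand (110 pairs) differed by a median of 0.50 in log2 fold, against 0.55 in random reassignments, at the 18.1th percentile of these.

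Differences between arms were larger than the counting error of independent reads. Of the 68 hairpins, 60.3% had a Fisher exact p under 0.05 for arm by library, where such counting error alone gives about 5%. PCR copies are not independent molecules, so uneven amplification can raise this share and is not excluded. A general gain of the less abundant arm is argued against, since the median difference between the less and the more abundant arm was 0.0619 (95% interval -0.28 to 0.26), below the bound of 0.3 set beforehand. A shift of all 5p arms against all 3p arms stays open, with a median difference of 0.117 and an interval from -0.11 to 0.40. A difference in adapter ligation or size selection between libraries, and a difference in arm choice or stability in the knockdown cells, cannot be told apart with 1 library per group and were not tested.

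miR-143-3p, miR-451a and miR-1-3p, abundant in tissues other than breast epithelium, were higher in the knockdown library, and a candidate explanation is RNA from another tissue or library; miR-143-3p is also on the p53-responsive list and miR-451a on the tamoxifen-response list, and 6 of the 26 markers of other tissues were at 10 TPM or more in the control. The 15 such markers under 10 mean TPM, pooled without these 3 miRNAs, had 241 reads against 111, a fold of 2.37 (1.88 to 2.99) above all of 10000 random sets matched on expression (percentile 100; the upper bound of their central 95% was 1.60), and 13 of the 15 were higher. This pool rests largely on miR-126-5p, miR-199a-5p and miR-145-5p (128 reads against 24), the last from the locus of miR-143-3p. The other arms of miR-126 and miR-199a were over 10 mean TPM and so not pooled. Of these, miR-126-3p was at 1.00 (0.952 to 1.06) and miR-199a-3p at 1.27 (0.941 to 1.72). The pool alone therefore does not separate added RNA from a difference between arms. Its other 12 markers gave 1.42 (1.06 to 1.90), at the 87.0th percentile of random sets of 12. They lay at the 99.7th percentile of random sets that also lost their 3 entries with the most added reads. Both comparisons were chosen after the values were seen. The other muscle markers gave 4.91 (1.02 to 46.7) on 9 and 2 reads, which reaches the interval of miR-1-3p, while the other fibroblast and smooth muscle markers gave 1.77 (1.42 to 2.22) and the other blood cell markers 1.44 (0.982 to 2.12), which met the bounds written for excluding these tissues, the fibroblast bound before and the blood bound after the values were seen. Both tissues nevertheless stay open, because added RNA adds reads and not folds, and a bound on folds is wrong for markers with a high baseline. Of the 133 control reads of the fibroblast markers, 84 and 32 were miR-199a-3p and miR-199b-5p, and of the 50 of the blood markers 40 were miR-486-5p. These baselines alone do not account for the fibroblast result. The other fibroblast markers under 3 TPM in the control gave 5.39 (3.17 to 9.69), still below 18.97, the lower bound of miR-143-3p. Such blood cell markers gave 3.05 (1.44 to 7.05), which reaches 3.49, the lower bound of miR-451a. The fibroblast value rests on 84 and 17 reads and depends on marker levels in the added RNA, which are not known. An effect of the knockdown stays open and untested.

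Of 11 pairs of miRNAs whose hairpins overlap on opposite strands, 7 had read counts within 2% in both libraries, among them miR-203a-3p and miR-203b-5p with 22162 reads each in the knockdown and 19561 each in the control library. The 11 are not all separate, since miR-103b, which has no arm in its name, entered with miR-103a-3p, miR-103a-1-5p and miR-103a-2-5p. In the knockdown library these 5p arms had 1 and 7 reads against 33391 of miR-103b. miR-103a-3p had 34170 reads there, and 37564 against 36210 in the control library, outside 2%, so miR-103b was never left out as a near-equal entry. The pair of miR-374b-3p and miR-374c-5p was far from equal, with 325 against 12 reads in the knockdown and 220 against 6 in the control library. Reads counted for both strands are a likely source of the near-equal counts. In 6 of the 11 pairs the counts differed by less than 0.43 times the square root of their sum in both libraries. Separate reads at equal levels would do so in 11.1% of pairs. Separate RNAs of similar level are argued against for the near-equal pairs as a set: leaving out the miR-3158 pair, whose outcome the 2% tolerance fixes, 10 of 12 library values of 6 pairs lay under this bound, against 5.56 expected from separate reads at equal levels once the choice of pairs within 2% is allowed for (Poisson-binomial probability of at least 10, with a normal approximation for each value, 0.00746). The exception is the pair of miR-7-5p and miR-3529-3p, which differed by 0.635 in the knockdown and 0.871 in the control library in these units. This bound therefore does not decide for that pair, because it takes equal levels of separate RNAs as given. Such RNAs would have to match as closely as 114846 against 114542 reads in the knockdown and 259233 against 258606 in the control library. The entries listed second in the near-equal pairs held 5.65% of control and 3.47% of knockdown reads, mostly miR-3529-3p, and so entered the TPM totals unequally.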
